A study of Pinus sylvestris with 36 samples.

How the data were processed

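The series measured transcript levels in roots of Scots pine (Pinus sylvestris) seedlings on 36 two-colour cDNA arrays. Seedlings were inoculated 14 days after germination and harvested 5 days later, per the labels. The 4 groups were roots mock-inoculated with water (control), roots with the root rot pathogen Heterobasidion annosum (pathogen), roots with the saprotroph Trichoderma aureoviride (saprotroph) and roots with the ectomycorrhizal fungus Laccaria bicolor (mycorrhiza). Per the labels' protocols, total RNA was turned into cDNA with a PCR-based kit that amplifies the cDNA, and the cDNA was labelled with Cy5 or Cy3 by a Klenow method. Each of the 3 replicates A, B and C has 12 arrays, which pair the 4 samples of that replicate in every combination and in both dye orientations. The 36 arrays therefore hold 12 RNA samples, 3 per group, and each RNA sample was read in 6 array channels. The labels do not say whether the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

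Each array has 1 deposited scanner file, which gives the Cy5 and Cy3 intensity and the local background of 6144 spots on a linear scale. Per the file headers the authors quantified the spots by a histogram method, with no background subtraction and no crosstalk correction. The deposited value table of the series holds a score for 6032 of the spots, and neither its scale nor its direction is stated in the sources used here. Set against the scanner values, the score equalled the log2 Cy3 intensity minus a constant, divided by the log2 Cy5 intensity minus another constant, with constants for each array, channel and print block. This form returned 100% of the values of 35 of the 36 columns within a tolerance of 0.001, relative to the size of the score. The column medians lay between 0.797 and 1.04. The score is a quotient of centred logs and not a log ratio, so it was used only as an alternative, after the centred logs had been recovered. The remaining column, that of the replicate A array with the pathogen in Cy5 and control in Cy3, was recovered for 0.332% of its values from its own scanner file. It was recovered for 100% from the scanner file of the replicate A array with the saprotroph in Cy5 and the pathogen in Cy3.

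The scanner files do not pair spots with gene names, and no probe annotation was used here. The 27 gene lists fixed before the data were examined, and the tests of their shift with their alternatives, were therefore not run. Probes are given by their spot numbers. The rule fixed for this case names, in each comparison, the 2 probes with the largest and the 2 with the lowest log2 fold change among those past the threshold that had 1 sign in all 3 replicates. The arrays have 48 print blocks of 128 spots, and neighbouring blocks held the same probes. The mean log intensities of the spots of block columns 1 and 2 correlated at r = 0.972 and those of columns 3 and 4 at r = 0.963, against r = 0.135 for columns 2 and 3. The pairing of spots was inferred from this layout and these values. The 2 spots of each probe were averaged. The 112 spots that the value table leaves out, which form 56 such pairs with a median log2 intensity of 7.57 against 11.73 for the other probes, were treated as control spots and left out of the tests. That left 3016 probes.

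The analysis used limma 3.58.1 in R 4.3.3. The background was corrected with normexp and an offset of 50. The log2(Cy5/Cy3) ratios were normalized within each array by loess, with control spots at weight 0. Spots that the scanner software marked as ignored were left out, which took between 0 and 1145 spots per array. Saturated spots were kept. The direction of each ratio was taken from the dyes in the labels. In each replicate a least-squares fit of its 12 arrays, with sample effects and a dye term per probe, gave 1 relative log2 level for each of the 4 RNA samples. Arrays of the same 2 extracts were thus never counted as replicates. The 12 levels per probe were then fitted in limma (lmFit, and eBayes with a trend) with group and replicate as terms, which left 6 residual degrees of freedom, and the prior added 5.72. The replicate term follows from the design, since ratios exist only within a replicate. Levels of single channels were not centred within replicates. Their deviations from the group means correlated between samples of the same replicate at r = 0.360 to 0.720 over 18 pairs. Between samples of different replicates r was -0.625 to 0.127 over 36 pairs. The deviations of a group sum to 0 over its 3 replicates, which by itself pushes this second range below 0. Any 2 samples of the same replicate share arrays, so effects of an array can by themselves push the first range above 0. Neither range therefore shows that the samples of a replicate are paired. The 6 comparisons between groups were two-sided and were adjusted with the Benjamini-Hochberg method over the 3016 probes, with a threshold of 0.05. A moderated F test covered the 3 contrasts against control. The fold changes of the fungi were correlated across probes beside 100 simulations of unchanged samples with the same residual spread and the shared control.

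The 2 steps were tested on simulated arrays with the dye terms and residual spread of the real ones, in which 200 of 3016 probes were changed. In pathogen vs control 73 of the 100 probes changed by a log2 value of 0.5 and 95 of the 100 changed by 1 were called in the right direction, beside 12 unchanged probes. In saprotroph vs control these counts were 67, 97 and 9, and in mycorrhiza vs control 68, 90 and 5. With no change, 0 probes were called in each of the 3 comparisons. The simulation gave every sample the same spread per probe, drew the probes independently, and added array noise to a residual spread that already holds it. Real samples can deviate over many probes at once. The 0 calls therefore do not measure the rate of false calls in the real data.

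Alternatives fixed before the data were examined covered the background correction, the within-array normalization, the filter on dim probes, spot flags, the authors' values, leaving out each replicate, the replicate term, single-channel levels, arrays as observations, the variance prior and a fold requirement. The planned filter kept probes above background in most of the 72 channels. It removed 0 probes, since every spot lay above its local background plus 2 background SD, with a local background of 0 for a median of 86.9% of spots in Cy5 and 58.8% in Cy3. The files hold 1 kind of flag, so leaving out every marked spot was already the main setting. Alternatives chosen after seeing the data, most of them once their counts had been seen in exploratory fits, used single-channel levels with the replicate term, kept the ignored spots, tested each spot by itself, left out the dimmest 25% of probes, left out the array with the mismatched column, gave each scan day its own dye term, and left out 3 arrays of replicate C, the mycorrhiza sample of replicate A or the mycorrhiza group. The precision of all values is limited by the number of arrays and samples.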

Results

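Transcript levels were measured in pine seedling roots 5 days after inoculation with a pathogen, a saprotroph or a mycorrhizal fungus, or with water. The 36 arrays carried 12 RNA samples, 3 in each of the 4 groups, and 3016 probes were tested. The median spot intensity per array ranged from 809 to 8670 in Cy5 and from 1200 to 11575 in Cy3. Between 0 and 49 spots per array were saturated in Cy5, and between 0 and 134 in Cy3. Log2 ratios of the 2 spots of a probe correlated at r = 0.363 to 0.850 within an array, with a median of 0.735.

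The dye swaps were used to check the labels of the arrays against each other within each replicate. An exchange of 2 group names throughout a replicate would leave these checks as they are, so they cannot exclude it. A pair of samples that differs little can give an r near 0 with any label. The dye term fitted for each probe correlated between replicates at r = 0.828 to 0.912 across probes. Only 5 of the 18 pairs of opposite dye orientation had log2 ratios with a correlation below 0 before the dye term was removed, and 16 of 18 had one afterwards. The 2 exceptions were control and saprotroph in replicate B (r = 0.10) and saprotroph and mycorrhiza in replicate C (r = 0.39). The dye term was fitted to the same arrays, and taking it out by itself pulls r somewhat below 0. Direct ratios of a pair correlated with the ratios through the other 2 samples at r = 0.338 to 0.879 in replicate A and 0.351 to 0.778 in replicate B. In replicate C the range was -0.0581 to 0.755, with the lowest value for control and saprotroph. When each array was predicted from the other arrays of its replicate, its own label gave the highest correlation of the 12 possible labels for 17 of the 36 arrays, one of the 3 highest for 31, and one below 0 for 3. The arrays of control and saprotroph in replicate B were above 0 at only r = 0.0640 and 0.0126. The 3 arrays below 0 belonged to replicate C and carried no pathogen sample. Without them limma called 111 probes in pathogen vs control, 99 of them among the 111 called with all arrays.

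The relative levels of the pathogen samples correlated most between replicates. Across probes their r was 0.451 (A and B), 0.516 (A and C) and 0.549 (B and C). For control these values were 0.376, -0.133 and 0.260, and for the saprotroph 6.5e-05, 0.177 and 0.373. For mycorrhiza they were -0.0450, -0.130 and 0.284. Levels are relative to the mean of the 4 samples of a replicate. A group that differs little from the others can thus have a low r even where its RNA is reproducible. Probes are not independent replicates, so these are descriptions of the samples. The mycorrhiza sample of replicate A had a wider spread of levels over probes (SD 0.28, log2) than the other 11 samples (SD 0.10 to 0.18).

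**Figure D1:**
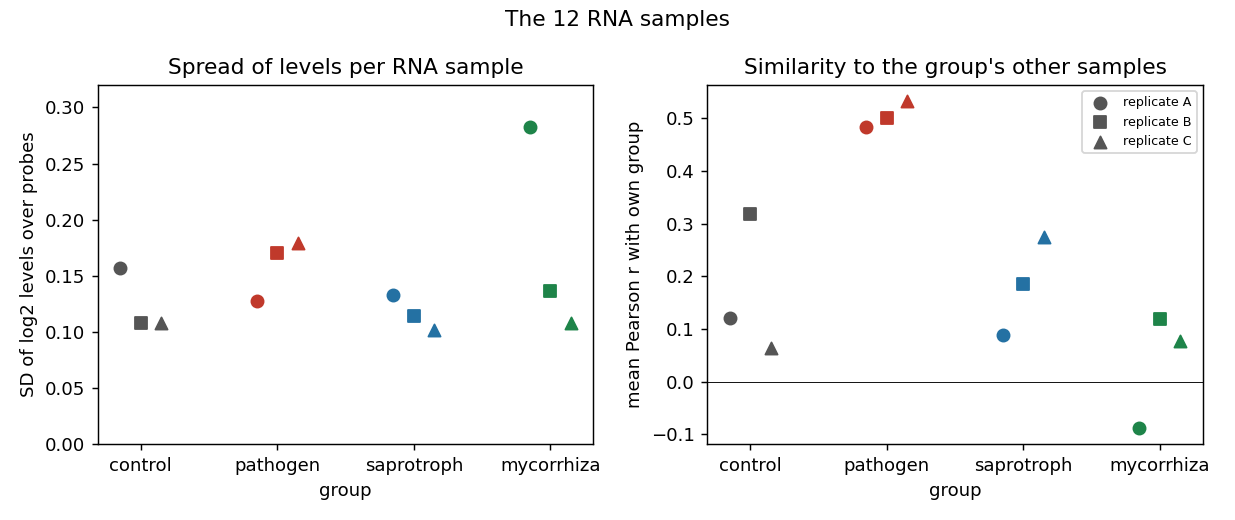
The 12 RNA samples by group, with a marker shape for each replicate. The left panel plots the SD of the relative log2 levels over 3016 probes, and the right panel plots the mean Pearson r with the other 2 samples of the group. The mycorrhiza sample of replicate A has the highest SD, 0.28, and the 3 pathogen samples have the highest mean r, 0.484 to 0.533.

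The first comparison asked which root transcripts differ after inoculation with the pathogen. In roots with Heterobasidion annosum 81 probes were higher and 30 were lower than in control roots, 3.68% of the probes tested. Among the higher probes the log2 fold change had a median of 0.52 and a range of 0.31 to 1.53, and among the lower probes a median of -0.42 and a range of -0.73 to -0.33. All 111 probes changed in 1 direction in all 3 replicates. The change passed a log2 value of 1 for 3 higher probes and 0 lower probes. The probe at spots 3625 and 3753 had the largest rise, with a log2 fold change of 1.53 ± 0.21 (SD, n = 3), a 2.89-fold higher level (limma adjusted p = 0.000116). The probe at spots 1320 and 1448 was higher by a log2 value of 1.33 ± 0.30 (SD, n = 3, limma adjusted p = 0.00256). The probe at spots 4889 and 5017 had a log2 fold change of -0.73 ± 0.24 (SD, n = 3, limma adjusted p = 0.0137), and the probe at spots 1406 and 1534 one of -0.61 ± 0.08 (SD, n = 3, limma adjusted p = 0.00869). Over 21 alternatives the calls of these 4 probes were lost in 4, 4, 8 and 6, in the order given, with highest limma adjusted p-values of 0.131, 0.360, 0.352 and 0.542. The 3 fits that called 0 probes are among them, and the probe at spots 3625 and 3753 also lost its call with no background subtraction, at a log2 fold change of 1.49 (limma adjusted p = 0.0675). None of the 4 was saturated in any of its 144 spot readings. The 2 spots of a probe gave fold changes that correlated at r = 0.851, and for all 111 probes both spots had the called direction. The call was made on the mean of the 2 spots. With each spot tested by itself, both spots were called for 54 of the 111 probes and at least 1 for 96. The higher probes had a median log2 intensity of 11.87 and the lower ones of 12.78, against 11.73 for all probes.

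The number of probes depended on the samples in the fit. Without replicate B or without replicate C, limma called 0 probes (297 and 247 at an unadjusted p under 0.05), without replicate A it called 181, of which 112 were higher and 69 lower, and without the mycorrhiza sample of replicate A alone it called 324, of which 178 were higher and 146 lower. Limma called 65 probes (58 higher, 7 lower) from single-channel levels with the replicate term, 12 (all higher) from those levels without it, and 0 from the authors' values (289 at an unadjusted p under 0.05), in which 1 column holds the data of another array. Without that array the authors' values gave 24.

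Slides were scanned on 6 days, and 1 array had no scan day. The scan day largely followed the pathogen samples. In replicate A no dated array with a pathogen sample shared its scan day with an array without it. In replicate B all arrays with a pathogen sample were scanned on the same day, and most others on other days. In replicate C all arrays without a pathogen sample were scanned on the same day, and most with it on another. With a dye term for each scan day, 63 probes were higher and 19 lower with the pathogen than in control, 69 of the 82 being among the 111. Within the 1 scan day per replicate that linked pathogen and control, the higher probes had a median log2 fold change of 0.38 in replicate A (5 arrays), 0.54 in replicate B (7 arrays) and 0.58 in replicate C (8 arrays). The lower probes had medians of -0.38, -0.47 and -0.43. These probes were called on arrays that include those of the scan day, so the direction of the medians is not independent of the call.

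**Figure D2:**
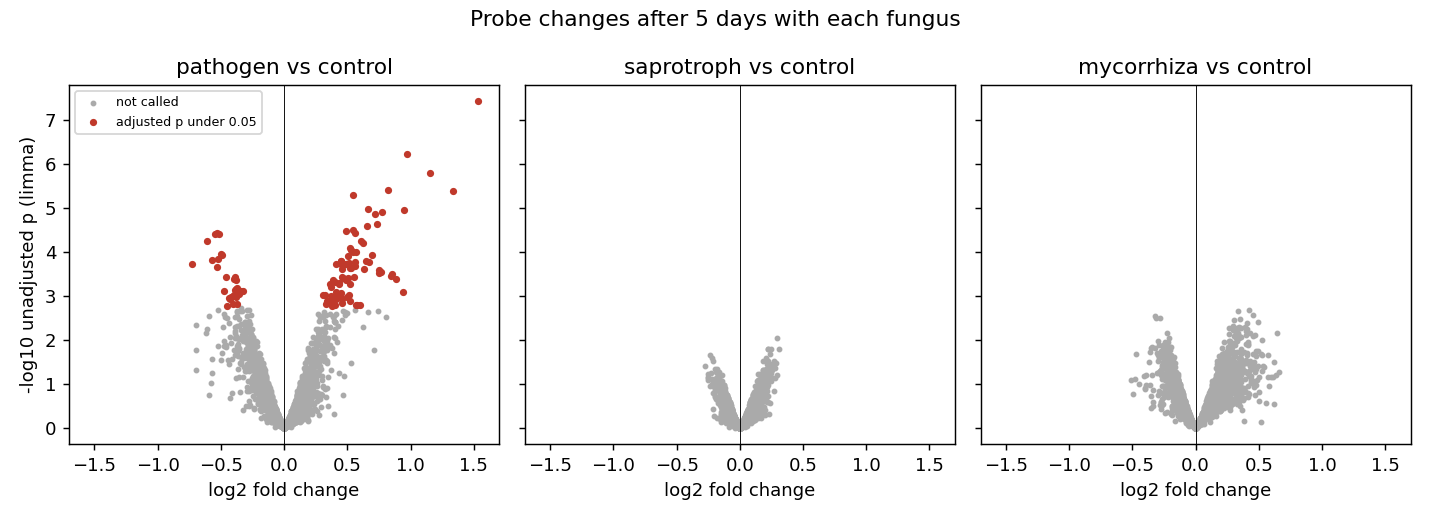
Log2 fold change against -log10 of the unadjusted limma p for 3016 probes, in 1 panel for each fungus against control. Red points are probes with an adjusted p under 0.05, of which there are 111 for the pathogen, 0 for the saprotroph and 0 for mycorrhiza.

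The second comparison set roots with the saprotroph against control roots. No probe passed the threshold: limma called 0 of 3016, with 29 at an unadjusted p under 0.05 where 150.8 would be the number by chance. The log2 fold changes lay between -0.27 and 0.31, and their SD over probes was 0.09, below the 0.19 of the pathogen comparison. The median SE of the shared fit was 0.0986, above this SD, so the shared error may be too wide for this comparison. A count below the number by chance therefore does not show that the roots had no response. The fold changes of the 3 replicates correlated across probes at r = 0.123, -0.200 and 0.235, against 0.640, 0.511 and 0.483 for the pathogen. Limma also called 0 when the mycorrhiza group was left out of the fit (104 at an unadjusted p under 0.05), and 0 with the 36 arrays taken as independent observations (140 at an unadjusted p under 0.05).

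The third comparison set roots with the mycorrhizal fungus against control roots. Limma called 0 of 3016 probes, with 281 at an unadjusted p under 0.05, and the smallest adjusted p was 0.491. The log2 fold changes lay between -0.51 and 0.66. The SD of the fold changes over probes was 0.42 in replicate A, 0.22 in replicate B and 0.16 in replicate C, and their correlations between replicates were r = 0.0906 (A and B), -0.319 (A and C) and 0.196 (B and C). Without the mycorrhiza sample of replicate A limma again called 0 probes, with 547 at an unadjusted p under 0.05. Of the fits tried on the tested probes, only that with the 36 arrays as independent observations called any, 197. In that fit arrays of the same extracts stand for replicates.

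The pathogen was also compared with each of the other fungi. Against the saprotroph 73 probes were higher and 34 lower in roots with the pathogen, and against mycorrhiza 79 were higher and 29 lower. The probes at spots 3625 and 3753 and at spots 1320 and 1448 had the largest rise in both. Their log2 fold changes were 1.51 ± 0.28 and 1.40 ± 0.30 (SD, n = 3) against the saprotroph, and 1.32 ± 0.41 and 1.35 ± 0.38 (SD, n = 3) against mycorrhiza. The limma adjusted p-values were 0.000139 and 0.00160 against the saprotroph, and 0.000595 and 0.00193 against mycorrhiza. Among the lower probes called against the saprotroph, the lowest fold changes were those of the probe at spots 1406 and 1534, at -0.60 ± 0.08 (SD, n = 3, limma adjusted p = 0.0111), and the probe at spots 1918 and 2046, at -0.59 ± 0.08 (SD, n = 3, limma adjusted p = 0.0123). Against mycorrhiza they were those of the probe at spots 5633 and 5761, at -0.87 ± 0.40 (SD, n = 3, limma adjusted p = 0.0240), and the probe at spots 4889 and 5017, at -0.70 ± 0.43 (SD, n = 3, limma adjusted p = 0.0163). All groups share 1 error in the fit, while the mycorrhiza sample of replicate A had the widest spread. The p-values of comparisons with mycorrhiza can thus be too small. At spots 4889 and 5017 the fit gave an SE of 0.136, where the replicates had log2 fold changes of -0.24, -0.75 and -1.10. Across all probes the fold changes against mycorrhiza correlated at r = 0.0647 (A and B), 0.114 (A and C) and 0.4995 (B and C). Their SD over probes was 0.367 in replicate A, 0.248 in replicate B and 0.254 in replicate C. Replicate A thus shared little with replicates B and C in this comparison. Against the saprotroph the correlations were r = 0.393, 0.431 and 0.513, in the same order. As for the comparison with control, limma called 0 probes in both without replicate B (283 and 360 at an unadjusted p under 0.05) or without replicate C (253 and 334), and more without replicate A or its mycorrhiza sample alone. The excess of higher probes was then gone, with 129 higher and 141 lower against the saprotroph and 113 and 115 against mycorrhiza without replicate A, and with 177 and 191 and 137 and 145 without that sample. Over 21 alternatives the calls against the saprotroph were lost in 4 for the probes at spots 3625 and 3753 and at spots 1320 and 1448, in 5 for that at spots 1406 and 1534 and in 7 for that at spots 1918 and 2046. Over 20 alternatives those against mycorrhiza were lost in 4 for the probe at spots 3625 and 3753, in 3 for that at spots 1320 and 1448, in 4 for that at spots 5633 and 5761 and in 8 for that at spots 4889 and 5017.

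**Figure D3:**
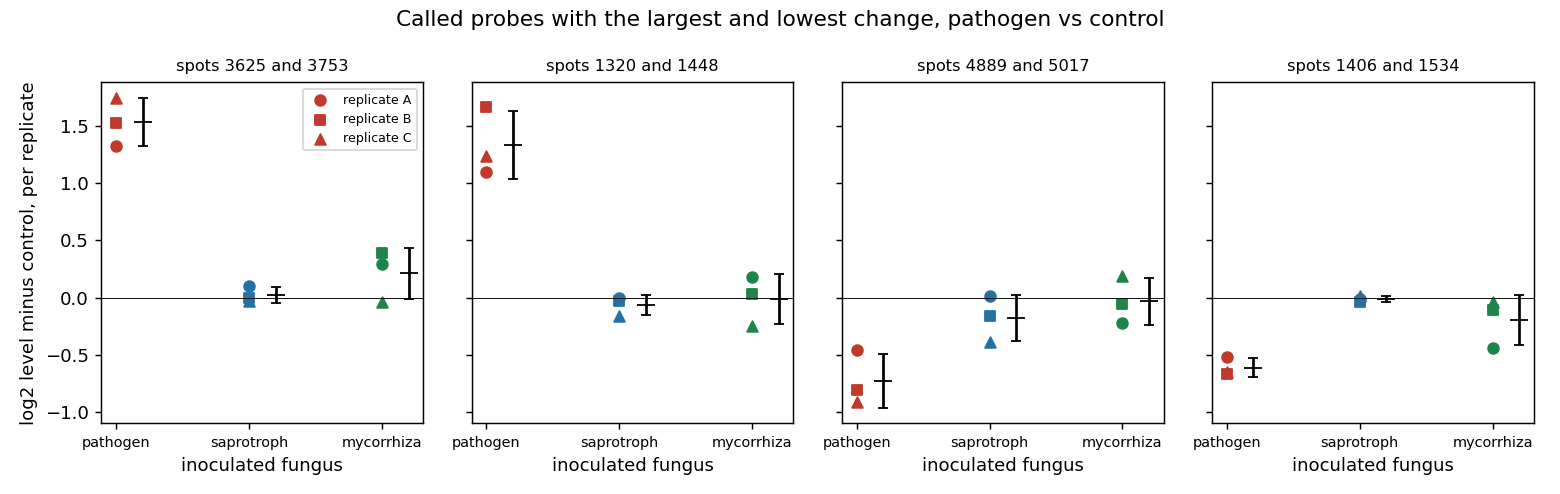
Log2 level minus control per replicate for the 2 probes with the largest and the 2 with the lowest change among those called in pathogen vs control, by inoculated fungus. Points are replicates A, B and C, and the bars are the mean ± SD (n = 3). The probe at spots 3625 and 3753 has a mean of 1.53 with the pathogen, 0.03 with the saprotroph and 0.21 with mycorrhiza.

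The 3 pathogen comparisons shared many calls. Called in all 3 were 55 higher and 12 lower probes. Of the 81 probes higher than in control, 66 were also higher than with the saprotroph and 60 also higher than with mycorrhiza, where independent lists of these sizes would share 1.96 and 2.12. Of the 30 lower probes 20 and 12 were shared, against 0.338 and 0.288. The comparisons share the pathogen samples, so part of the overlap may come from them. Unchanged samples simulated with that sharing gave 0.0200 and 0 shared calls on average, but hardly any calls to share, so the simulation does not measure that part. In the saprotroph samples the 81 probes had a median log2 fold change against control of 0.03 (SD 0.03 over the 3 replicates), and in the mycorrhiza samples one of 0.01 (SD 0.08). The 30 lower probes had medians of -0.03 (SD 0.05) with the saprotroph and -0.13 (SD 0.10) with mycorrhiza, where 25 of 30 lay below 0. Both sets were called against the same control samples, which moves these medians in the called direction with no change in the other fungi.

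Between the saprotroph and mycorrhiza limma called 0 probes, with 186 at an unadjusted p under 0.05 and a smallest adjusted p of 0.693. With the 36 arrays as independent observations it called 159. The F test among the 4 groups called 78 probes, and all 78 had also been called in at least 1 of the 3 pathogen comparisons. The pathogen had the highest level of the 4 groups at 60 of them and the lowest at 18. The F test called 0 probes without replicate B or without replicate C (209 and 241 at an unadjusted p under 0.05), and 299 without the mycorrhiza sample of replicate A.

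Fold changes against control were correlated between fungi across probes. The correlation was r = 0.276 for pathogen and saprotroph, 0.369 for pathogen and mycorrhiza, and 0.336 for saprotroph and mycorrhiza. Unchanged samples with the shared control gave 0.502, 0.498 and 0.501, each above the observed value. Without the mycorrhiza sample of replicate A the order turned for saprotroph and mycorrhiza, at r = 0.647 against a simulated 0.432, and not for pathogen and mycorrhiza, at 0.318 against 0.432. The simulation gave every group the same spread. The observed fold changes against control had SDs of 0.191 (pathogen), 0.0864 (saprotroph) and 0.161 (mycorrhiza). A wider spread in 1 fungus can lower r, so an r below the simulated value does not show unlike responses. The covariances were 0.00455, 0.0113 and 0.00468 against 0.00847, 0.00841 and 0.00842 in the simulation, whose residual spread includes the mycorrhiza sample of replicate A. Without that sample the covariances were 0.00455, 0.00922 and 0.00851 against 0.00437, 0.00438 and 0.00437. Part of each value may come from the shared controls. Fold changes of 2 fungi taken from different replicates share no sample, and over 6 such pairings their covariances averaged 0.00220, 0.00495 and -0.00127.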

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

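The tests of spots outside the authors' table, of single probes in both dye orientations, of fungal RNA (higher and lower probes), of a wrong group label and of the mycorrhiza group left out together with replicate B or C were chosen only after the results they bear on had been seen.

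Signal in spots outside the authors' table was examined because no comparison above used it. Of the 56 pairs, adjusted over these pairs alone, limma called 1 in pathogen vs control, 1 in mycorrhiza vs control, 2 in pathogen vs saprotroph and 2 in saprotroph vs mycorrhiza. They were 3 different pairs. The pair at spots 277 and 405 had a log2 fold change of -0.50 ± 0.17 (SD, n = 3) in pathogen vs control (adjusted p = 0.0128) and a mean log2 intensity of 10.12. The pair at spots 5732 and 5860 had one of 0.57 ± 0.33 (SD, n = 3) in mycorrhiza vs control (adjusted p = 0.0376), at a log2 intensity of 7.38, close to the median of these pairs. What these spots hold was not analysed here.

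For the probes called in pathogen vs control, a probe-specific dye effect left in the ratios would show in one dye orientation and be absent or turned in the other. In the called direction the median log2 ratio of the 111 probes on the direct arrays was 0.53 with the pathogen in Cy3. With the pathogen in Cy5 it was 0.47. Each was above its SD over replicates (0.11 and 0.09), and 111 of the 111 probes were above 0 in both orientations. The probes were called in a fit that includes the direct arrays in both orientations, with a dye term per probe. Their direction on these arrays is therefore not independent of the call, and the test leaves a dye effect open. RNA of the fungus hybridizing to the probes would raise them, and 30 probes were lower, more than the 5% of false calls that the threshold allows. This argues against it only as a direct source of the lower probes. Ratios are relative within an array, so the sign alone does not exclude an indirect share. For the higher probes it stays open: those higher with the pathogen than with the saprotroph had a median of -0.0209 in mycorrhiza vs control, which shares no sample with that comparison, but the amount of each fungus in the roots is not known and the probes have no names here. A response of the root to the pathogen, the difference the design names, also stays open.

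The mycorrhiza sample of replicate A stood apart, with an SD of at least 0.277 when any 1 of its 6 arrays was left out and of 0.276 after a trend on intensity was removed. The highest SD of the other 11 samples was 0.179, so these values argue against 1 faulty array and an intensity trend as the whole cause. Another of the 4 group names would leave its SD of 0.282 as it is, so a wrong label would not account for the spread. For the same reason the SD cannot show whether the label is right. For its low correlation with its own group (mean r = -0.0875) a wrong label cannot be told apart from other sources, since its levels correlated at r = 0.272 with the mean control levels of replicates B and C, but at 0.0209 with B and 0.412 with C, and at -0.103 with the mean of the other 2 mycorrhiza samples. The value of 0.272 lies under a bound of 0.3 that would have excluded a wrong label, and the spread between B and C was allowed for only after it was seen. An exchange with control needs a partner, but the control sample of replicate A correlated at -0.0478 with the mycorrhiza mean of B and C, against 0.154 with control and 0.503 with the saprotroph, values that centring within the replicate ties together, and a real difference of these roots was not tested. An exchange of the control and saprotroph names in replicate A was not tested either.

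Limma called 0 probes in pathogen vs control without replicate B or replicate C (297 and 247 at an unadjusted p under 0.05), and 181 without replicate A. The spread of the mycorrhiza sample of replicate A may be the reason in the first case, since that sample widens the error of every comparison in a shared fit. With the mycorrhiza group left out as well, 264 probes were called without replicate B, against 342 with all replicates in a fit of the same form. Without replicate C the same step gave 33 against 342, so it leaves open what else contributes there.

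Divisions of the 6 samples of a comparison into 3 and 3 number 10, the real one included, too few for a share under 0.05. Since the replicate letters pair the samples, only 3 of the others part every replicate as the real one does, and the other 6 keep both samples of a replicate on one side. The real division gave 111 probes in pathogen vs control, 107 in pathogen vs saprotroph and 108 in pathogen vs mycorrhiza, and the highest other division of either kind gave 0 in each. In saprotroph vs control, mycorrhiza vs control and saprotroph vs mycorrhiza the real division and the highest other gave 0, with 29, 281 and 186 probes at an unadjusted p under 0.05 by limma. For the F test, 5 of 100 assignments of the group names within replicates gave as many probes as the real one, the real one included, so chance is not excluded by this test. The highest other gave 89 against 78. The 4 others that gave as many were among the 8 that kept the pathogen samples together, and the highest count among the 91 that did not was 0.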

How the results depend on the processing

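The alternatives were fixed before the data were examined, except single-channel levels with the replicate block, ignored spots kept, each spot by itself, the dimmest 25% of probes left out, the authors' values without 1 array, the scan day term, and fits without 3 arrays of replicate C, the mycorrhiza sample of replicate A or the mycorrhiza group. These were chosen after seeing the data, most of them once their counts had been seen in exploratory fits.

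The 111 probes of pathogen vs control kept their direction in every alternative in which all were tested, except that spots tested singly were not matched, and 93 of 93 kept it without the dimmest probes. The named probes gave 248 values under the alternatives, of which 187 stayed past the threshold, 61 did not and 0 turned direction. For both sets the direction was fixed beforehand in fits without a replicate, since every probe had 1 sign in all 3 replicates. Alternatives that change only the error or the prior leave the fold change as it is. Kept directions are therefore no test in those alternatives. Saprotroph vs control gave 0 probes in limma in each alternative, with 6 to 140 at an unadjusted p under 0.05. The planned gene list alternatives were not run, the planned filter on dim probes removed 0 probes, and the planned flag alternative was the setting already used. Every spot lay above its local background, but its correction ended named calls, 3 with no subtraction (spots 3625 and 3753 in the 3 pathogen comparisons) and 2 with plain subtraction (spots 4889 and 5017). Where no reason is given below, the cause was not tested.

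Counts that moved by over 1.5 times are given for pathogen vs control, pathogen vs saprotroph, pathogen vs mycorrhiza and the F test, in that order. Over fits without a replicate or without the mycorrhiza sample of replicate A the ranges were 0 to 324, 0 to 368, 0 to 282 and 0 to 299. Without the mycorrhiza group the first 2 were 342 and 370. The replicate block followed from the design. With no replicate block the counts were 274, 275, 264 and 232, because levels already centred within replicates then count degrees of freedom that they do not have. Single-channel levels with no replicate block gave 12, 9, 10 and 6, and with the block 65, 53, 47 and 49. The block changed no call in saprotroph vs control, mycorrhiza vs control or saprotroph vs mycorrhiza, which gave 0 with and without it. Arrays as independent observations, which count the same extracts several times, gave 563, 567, 599 and 875, with 197 for mycorrhiza vs control and 159 for saprotroph vs mycorrhiza. The authors' values gave 0, 0, 0 and 0 in limma (289, 329, 364 and 351 at an unadjusted p under 0.05), and without 1 array 24 (21 higher), 7, 57 and 6. Print-tip loess gave 172 for pathogen vs saprotroph. Each spot by itself gave 186, 179 and 198 for the first 3, counts of single spots out of 6030 and not of probes out of 3016. A log2 fold change of at least 1 as well left 3 in each by construction.

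The correlation of fold changes of saprotroph and mycorrhiza was 0.167 with print-tip loess, 0.171 with median centring only, 0.184 with the authors' values, 0.206 with these without 1 array and 0.431 with ignored spots kept. Over the fits without a replicate or sample it ranged from 0.107 to 0.647, that of pathogen and mycorrhiza from 0.286 to 0.476, and that of pathogen and saprotroph from 0.111 (without replicate A) to 0.369.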

Other observations

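The comparisons across replicates below were chosen after the data were seen.

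Correlating the fold changes of one fungus in one replicate with those of another fungus in a different replicate leaves no shared sample. Over the 6 such pairings the r across probes had a median of 0.111 (range -0.214 to 0.302) for pathogen and saprotroph, 0.0834 (-0.178 to 0.342) for pathogen and mycorrhiza, and 0.0142 (-0.519 to 0.546) for saprotroph and mycorrhiza. Of the 6, 4, 3 and 3 were above 0. The mean covariances were 0.00220, 0.00495 and -0.00127. For one fungus against itself in another replicate they were 0.0280 for the pathogen (range 0.0252 to 0.0294), 0.000637 for the saprotroph (-0.00478 to 0.00418) and -0.00211 for mycorrhiza (-0.0214 to 0.00820). 

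The probes called in each pathogen comparison were also looked up in the comparison of the remaining group pair, where the pathogen samples take no part. The medians of the higher probes were -0.0209 in mycorrhiza vs control (SD 0.05 over the 3 replicates), 0.00444 in saprotroph vs control (SD 0.02) and 0.00979 in saprotroph vs mycorrhiza (SD 0.12), each within its SD. Those of the lower probes were -0.0179 in mycorrhiza vs control (SD 0.09), 0.0293 in saprotroph vs control (SD 0.02) and 0.0860 in saprotroph vs mycorrhiza (SD 0.05). The last came from the 30 probes lower than in control, and 26 of them were above 0. Its 3 replicate medians were above 0, as were those of the 29 probes lower than with mycorrhiza.

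The authors' column for the replicate A array with the pathogen in Cy5 and control in Cy3 was recovered in full from the scanner file of another array, as described for the processing. With the values as deposited limma called 0 probes in pathogen vs control (289 at an unadjusted p under 0.05), and without that array 24. The ratios in its scanner file correlated at r = 0.539 with those predicted from the other arrays for its own label, the highest r of the labels tried.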
